A study of Mus musculus with 6 samples.

How the data were processed

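The series holds bulk RNA sequencing of epithelial cells sorted from mouse small-intestinal crypts, with 3 libraries of tdTomato-positive cells from Hopx-CreER mice and 3 libraries of eGFP and tdTomato double-positive cells from Lgr5-CreER mice. Per the labels, cells were sorted into TRIzol LS, RNA was cleaned on RNeasy MinElute columns, and libraries were made by SMART-Seq amplification and Nextera XT tagmentation, which do not mark the strand. The authors deposited 1 table of raw counts for the 6 libraries, as whole numbers per versioned mouse Ensembl gene, with no normalization applied. Per the submitters' processing notes, kallisto, edgeR and the build GRCh38 were used, with no role, version or order. GRCh38 is a human build and the identifiers are mouse, so that name does not describe this table. Whether kallisto estimates were rounded, or reads were counted otherwise and on which strand, is not given in the sources used here.

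The table held 23565 genes, of which 2443 were at 0 in every library. Gene symbols, positions and types came from the GENCODE M21 annotation (GRCm38), which matched 23479 identifiers and left 86 unmatched. Every column of the table was used. Columns state the sorting gate but no replicate number, so libraries are numbered by column order and the numbers are names only. Library totals ran from 10839306 to 14570555 counts, so that 1 count was worth 0.067 to 0.093 CPM (counts scaled by library size with TMM factors) and 3 counts 0.20 to 0.28 CPM. The 10 most abundant genes took 5.33% to 7.01% of a library. Amplified reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only.

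Groups were compared by the edgeR (4.0.16) quasi-likelihood F-test in R 4.3.3, with TMM normalization, the default filterByExpr filter, and Benjamini-Hochberg adjustment over the 12439 genes tested at a threshold of 0.05. Positive log2 fold changes are higher in Hopx-CreER cells. The SE of a log2 fold change was taken from its F statistic, and SDs are between the 3 libraries of a group. The biological coefficient of variation was 22.5%. For Hopx and Lgr5, an exact two-sided permutation test on CPM was also run. For genes with 1 to 3 counts in a group, the ratio of summed counts is given with an exact 95% interval. Principal components used log2 CPM with a prior count of 2.

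Gene lists, tests, alternatives and the rule for named genes were chosen before the data were examined. The 30 lists cover stem, Paneth, goblet, enteroendocrine, tuft and enterocyte cells, cell cycle phases, signalling, metabolism, stress, MHC class II and interferon genes, other cell types that the gates could hold, intestinal region, and mitochondrial and sex-linked genes. Lists with at least 3 tested members, 29 in number, were tested by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, again with a correlation estimated from the data, and by fry, with adjusted p-values over the lists. Camera compares a list with all other genes, while fry asks whether a list's genes move one way on balance. With an estimated correlation, camera also takes its p-value on the few residual degrees of freedom that 6 libraries leave, so it is stricter on that account too. The named genes are Hopx and Lgr5; the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between groups, without predicted genes and pseudogenes as judged by symbol; and the members with the smallest p at a mean of at least 1 CPM, up to 3 from each list of stem cells, differentiated intestinal epithelial cell types and cell cycle phases, and up to 2 from each other list. This gave 75 genes, not all of which are printed, and BC002163 passed the symbol rule although the annotation calls it a pseudogene. Other genes are said to be named after their values were seen.

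Alternatives were RLE factors, library totals alone, upper quartile factors, DESeq2 1.42.0, limma-voom with and without quality weights, other count filters (none, at least 1 CPM in 3 libraries, at least 10 counts in each library of a group), a threshold of 0.01, a log2 fold change of at least 1, glmTreat against a fold of 1.5, leaving out each library, and leaving out the Paneth list with the 10 most abundant genes, or mitochondrial and ribosomal protein genes. Added after the data were seen were offsets for transcript GC content (spline with 5 degrees of freedom per library, longest transcript), the sum of the 2 Lgr5-CreER columns that share a number, and that sum with Hopx-CreER library 3 left out.

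The procedure was tested on simulated data of the same size, with 12439 genes of which 200 were changed. Of the genes given a fold of 1.5, 2 and 4, 11.9%, 52.2% and 83.3% were called, with median estimated folds of 1.52, 2.04 and 4.06, and 9.26% of the 108 calls were not among the changed genes. With nothing changed, edgeR made 0 calls. At a fold of 4, limma-voom called 83.1% and DESeq2 89.2%. Of 20 random lists, camera called 0 and fry 1, and the raised list had a camera adjusted p of 1.69e-95. Genes were simulated independently of each other, while correlations estimated from the data reached 0.948. The simulation therefore cannot show how camera with the preset correlation does on lists of correlated genes. A simulated GC trend of 1 library had a correlation of 0.70 across genes before the GC offsets and -0.0023 after.

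Reads are hard to assign within the Defa defensin genes, the H2 genes, the Hspa1a and Hspa1b pair, and between BC002163 and related loci, so values of single members there are uncertain.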

Results

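RNA sequencing counts were measured in 6 libraries of cells sorted from mouse small-intestinal crypts. The mice carried a tamoxifen-inducible Cre recombinase (CreER) at the Hopx or the Lgr5 locus, together with a Rosa26 reporter that makes the red fluorescent protein tdTomato once Cre has acted. Lgr5, a receptor for R-spondins, marks the crypt base columnar stem cell, and Hopx, an atypical homeodomain protein, has been used to mark cells higher in the crypt that are thought to act as reserve stem cells. Crypts were collected 16 hours after 1 mg of tamoxifen, and the series description gives 3 mice of each genotype. The Hopx-CreER group held 3 libraries of tdTomato-positive cells, and the Lgr5-CreER group held 3 libraries of cells positive for tdTomato and for the eGFP that the Lgr5 allele also makes. Library totals were 13728768, 12190734 and 11447879 counts for Hopx-CreER libraries 1, 2 and 3, and 14570555, 10839306 and 14171015 counts for Lgr5-CreER libraries 1, 2 and 3, numbered by their order in the count table. The column names of Lgr5-CreER libraries 2 and 3 share a number and no label ties a library to a mouse, so whether these came from separate mice, as the description would have it, could not be checked. Every p-value rests on the 6 libraries being independent. Over genes with a mean of at least 10 CPM, log2 differences between those libraries had an SD of 0.258, against 0.325 to 0.587 for the other pairs within a group.

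The comparison asked how the transcripts of cells marked through Hopx differ from those of cells marked through Lgr5. Genotype and sorting gate differed together, so their effects cannot be told apart. Only the Lgr5-CreER cells were also gated on eGFP from the Lgr5 allele, so higher Lgr5 RNA in them can be set in part by the sort. Hopx-CreER cells carried more RNA of Paneth, goblet, enteroendocrine, tuft and enterocyte genes, and less RNA of Lgr5 stem cell and Wnt target genes. Each library is of bulk RNA, so here and below a different mix of cell types cannot be told from a different level within cells. Genes of fatty acid oxidation, glycolysis, oxidative phosphorylation and the immediate early response were higher as lists in Hopx-CreER cells, and those of G1/S, ribosome biogenesis and MHC class II were lower. These list calls are by camera with a preset correlation, and none held at an adjusted p under 0.05 with an estimated correlation (smallest 0.0521). That setting also uses few residual degrees of freedom, so the loss of calls is not due to correlated genes alone. Of 12439 genes tested, 1586 (12.8%) changed at an edgeR adjusted p under 0.05, of which 1176 were higher in Hopx-CreER cells and 410 were higher in Lgr5-CreER cells. At an unadjusted p under 0.05, 3402 genes passed. A log2 fold change of at least 1 was reached by 770 of the former and 169 of the latter. The median log2 fold change was 1.47 among genes called higher in Hopx-CreER cells, -0.91 among those called lower, and -0.033 among all tested genes. All 3 libraries of one group lay above all 3 of the other for 1576 of the called genes, and for 34.9% of all tested genes, where chance gives 10%.

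The first principal component held 58.6% of the variance and parted the groups, with the Hopx-CreER libraries at 27.8, 35.7 and 66.3 and the Lgr5-CreER libraries at -43.7, -49.1 and -37.2. Hopx-CreER library 3 stood apart on the second component (18.1%), at -39.9 against 24.6 and 34.1 for libraries 1 and 2. Across genes, its deviation from libraries 1 and 2 followed transcript GC content (Spearman rho 0.473). The count of changed genes was 1868 without it. Leaving out Lgr5-CreER library 1, 2 or 3 gave 944, 723 or 882 changed genes, of which 744, 606 or 722 were higher and 200, 117 or 160 lower in Hopx-CreER cells. Without Hopx-CreER library 2, 218 genes were lower in Hopx-CreER cells. DESeq2 called 1413 genes higher and 670 lower in Hopx-CreER cells. Library totals alone as scaling (median of all genes shifted by -0.114) gave 938 and 729, and offsets for GC content gave 1044 and 1028. The share of calls higher in Hopx-CreER cells was thus 74.1% in the main test, 56.3% with library totals alone and 50.4% with GC offsets. Across tested genes the log2 fold change followed GC content (Spearman rho 0.25, and 0.0852 without Hopx-CreER library 3). With the 2 columns that share a number summed into 1 library, 790 genes changed, and 1393 changed with Hopx-CreER library 3 also left out.

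Both genes that carried the Cre were lower in Hopx-CreER cells, Hopx included. Hopx (ENSMUSG00000059325.14; protein coding, minus strand of chromosome 5, 77086988 to 77115121, GRCm38) stood at 54.3 ± 9.65 CPM (counts scaled by effective library size; SD, n = 3) in Hopx-CreER cells and at 89.8 ± 3.94 CPM in Lgr5-CreER cells, 1.66-fold higher in the latter. Lgr5 (ENSMUSG00000020140.15; protein coding, minus strand of chromosome 10, 115450311 to 115587780) stood at 41.4 ± 17.7 CPM (SD, n = 3) against 107.8 ± 3.93 CPM, 2.6-fold higher in Lgr5-CreER cells. Hopx was 44.9, 64.2 and 53.7 CPM in the Hopx-CreER libraries and 94.3, 87.9 and 87.1 CPM in the Lgr5-CreER libraries, and Lgr5 was 52.8, 50.3 and 21 CPM against 103, 110 and 110 CPM. The log2 fold change, Hopx-CreER over Lgr5-CreER, was -0.73 ± 0.15 (SE) for Hopx (edgeR adjusted p 0.0131) and -1.38 ± 0.29 for Lgr5 (edgeR adjusted p 0.0147). The labels do not say whether the targeted Hopx allele still makes Hopx transcript. An exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 allows. Leaving out 1 library ended the Hopx call without Lgr5-CreER library 1 (edgeR adjusted p 0.0536) or 2 (0.0541). It ended the Lgr5 call without Lgr5-CreER library 2 (edgeR adjusted p 0.0576) or 3 (0.0537). The log2 fold changes in these fits moved little, to -0.69 and -0.75 for Hopx and -1.37 and -1.37 for Lgr5. A left-out library also costs residual degrees of freedom, so here and below an ended call need not rest on that library. Summing the columns that share a number also ended both calls, and over all alternatives the adjusted p ran from 0.000463 to 0.0541 for Hopx and from 1.86e-05 to 0.0585 for Lgr5.

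**Figure D1:**
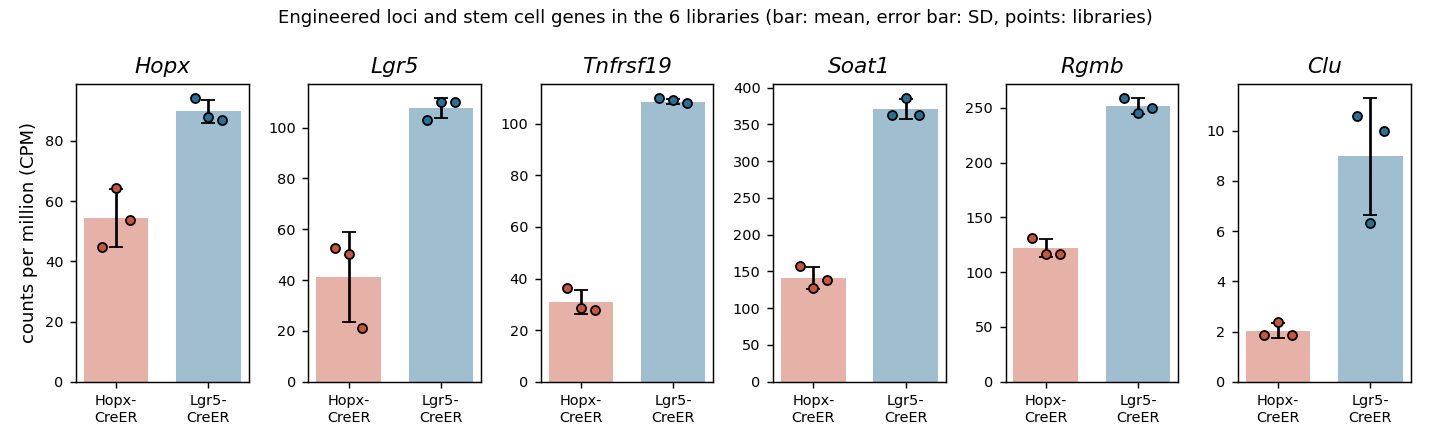
CPM on linear axes from 0 for Hopx, Lgr5, Tnfrsf19, Soat1, Rgmb and Clu in each group, with bars for the mean, error bars for the SD and points for the 3 libraries. In each panel the Lgr5-CreER libraries lie above the Hopx-CreER libraries, as for Tnfrsf19 at 108 to 110 CPM against 27.9 to 36.2 CPM.

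Lgr5 stem cell genes were lower in Hopx-CreER cells throughout the list. Tnfrsf19, a receptor tied to Wnt signalling in crypt stem cells, fell by 1.81 ± 0.14 (SE) on the log2 scale (30.9 ± 4.6 against 108.5 ± 1.03 CPM, SD, n = 3; edgeR adjusted p 0.000374). Soat1, an enzyme that esterifies cholesterol, fell by 1.39 ± 0.11 (edgeR adjusted p 0.000374), and Rgmb, a BMP co-receptor, by 1.04 ± 0.10 (edgeR adjusted p 0.000569). Olfm4, a secreted stem cell marker named here after its values were seen, was 2661 ± 810 CPM against 7543 ± 242 CPM (SD, n = 3). Of the 29 tested members (30 listed), 23 were lower, 0 higher and 6 did not pass, and 29 were lower when adjusted over the list alone. For the stem cell list, whose median log2 fold change was -1.04, the camera adjusted p was 5.76e-27, and adjusted p = 0.0521 with an estimated correlation. The lower count was 14 without Lgr5-CreER library 2 and 15 without Lgr5-CreER library 3.

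Reserve stem cell genes did not rise as a group in Hopx-CreER cells. Krt19, an epithelial keratin, was higher by 0.96 ± 0.13 (SE, log2; edgeR adjusted p 0.0022), while Clu, a secreted chaperone, fell by 2.14 ± 0.33 (2.04 ± 0.29 against 8.98 ± 2.34 CPM, SD, n = 3; edgeR adjusted p 0.00388). Lrig1, a negative regulator of ErbB signalling, fell by 0.69 ± 0.13 (edgeR adjusted p 0.0101), and Hopx was the remaining lower gene. Bmi1 and Tert, other markers proposed for these cells and named after their values were seen, had log2 fold changes of -0.61 ± 0.37 (edgeR adjusted p 0.328) and -0.32 ± 0.34 (0.587). Of the 12 tested members, 1 was higher, 3 were lower and 8 did not pass, with 1 higher and 5 lower when adjusted over the list alone, and 5 were lower with GC offsets. For the reserve list, the median was -0.62 and the camera adjusted p 0.0204, and adjusted p = 0.162 with an estimated correlation. Without Hopx-CreER library 3, the median was -0.38 and the camera adjusted p 0.0522, within a range of 0.00612 to 0.162 over the alternatives.

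Wnt target genes were mostly lower in Hopx-CreER cells. Ascl2, a transcription factor of the Lgr5 stem cell, fell by 1.09 ± 0.15 (SE, log2; edgeR adjusted p 0.00239), and Tnfrsf19 belongs to this list too. The single higher member, named after its values were seen, was Wif1, a secreted Wnt inhibitor. It had 94 counts in Hopx-CreER libraries against 3 in Lgr5-CreER libraries, a ratio of 35.8 (95% interval 11.9 to 177). Such intervals cover counting error only. Of the 17 tested members (21 listed), 1 was higher, 11 were lower and 5 did not pass, and 1 was higher and 14 lower when adjusted over the list alone. For the Wnt list, the median was -0.80 and the camera adjusted p 2.04e-10, and adjusted p = 0.0957 with an estimated correlation. The list shares 10 of its tested genes with the Lgr5 stem cell list, and 1 each with the reserve, the cell cycle inhibitor and the immediate early lists. The only lower members outside the stem cell list, named after their values were seen, were Tcf7, Myc and Apcdd1. They kept their calls in 6, 4 and 0 of the 6 fits that left out 1 library, so the fall was mostly that of stem cell genes. The lower count of the Wnt list was 6 without Lgr5-CreER library 2 and 6 without Lgr5-CreER library 3.

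Paneth cell genes showed large rises in Hopx-CreER cells. Defa30 and Defa24, which encode antimicrobial alpha-defensins, rose by 4.14 ± 0.34 and 3.27 ± 0.31 (SE, log2; edgeR adjusted p 0.000379 and 0.000548), to 1598 ± 643 and 5434 ± 1992 CPM (SD, n = 3) from 90.5 ± 27.5 and 561.7 ± 192 CPM. Clps, which encodes colipase, rose by 3.91 ± 0.34 (edgeR adjusted p 0.000439). Reads can be shared within the alpha-defensin family, so the split between its members is uncertain. Fgfrl1, the single lower member and named after its values were seen, fell by 0.79 ± 0.15 (edgeR adjusted p 0.00949). Of the 23 tested members (27 listed), 20 were higher, 1 was lower and 2 did not pass, with 21 higher and 1 lower when adjusted over the list alone. For the Paneth list, the median was 3.27 and the camera adjusted p 2.02e-32, and adjusted p = 0.0992 with an estimated correlation. The list took 1.72%, 1.68% and 3.42% of all counts in Hopx-CreER libraries 1, 2 and 3, against 0.199%, 0.391% and 0.226% in the Lgr5-CreER libraries, and its median without Hopx-CreER library 3 was 2.79.

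Goblet cell genes rose in Hopx-CreER cells by smaller amounts. Muc2, the gel-forming mucin of the intestine, rose by 2.02 ± 0.19 (SE, log2; 130 ± 29.4 against 32.1 ± 4.01 CPM, SD, n = 3; edgeR adjusted p 0.000548). Spink4, a secreted goblet cell peptide, rose by 2.02 ± 0.20 (edgeR adjusted p 0.000615), and Klk1, a kallikrein protease, by 1.90 ± 0.11 (edgeR adjusted p 0.000212). Foxa3, a transcription factor of secretory cells and the single lower member, named after its values were seen, fell by 0.46 ± 0.12 (edgeR adjusted p 0.0379). Its call ended without Hopx-CreER library 1 or without Lgr5-CreER library 1, 2 or 3, at adjusted p of 0.0873 to 0.14, so that 0 members were then lower. Of the 23 tested members (24 listed), 13 were higher, 1 was lower and 9 did not pass, with 17 higher and 1 lower when adjusted over the list alone. For the goblet list, the median was 1.34 and the camera adjusted p 5.71e-17, and adjusted p = 0.151 with an estimated correlation.

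Enteroendocrine genes rose broadly in Hopx-CreER cells. Chga, which encodes the granule protein chromogranin A, rose by 4.82 ± 0.30 (SE, log2), from 61.8 ± 11.7 to 1745 ± 630 CPM (SD, n = 3; edgeR adjusted p 0.000212). Reg4, a secreted lectin, rose by 5.21 ± 0.34 (1641 ± 682 against 44.5 ± 7.06 CPM; edgeR adjusted p 0.00024). Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, rose by 4.15 ± 0.34 (edgeR adjusted p 0.000379). Of the 32 tested members (34 listed), 26 were higher, 0 lower and 6 did not pass, and 30 were higher when adjusted over the list alone. For the enteroendocrine list, the median was 2.85 and the camera adjusted p 2.16e-29, and adjusted p = 0.151 with an estimated correlation. The higher count was 17, 19 and 18 without Lgr5-CreER libraries 1, 2 and 3, and 18 without Hopx-CreER library 2.

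Tuft cell genes were higher in Hopx-CreER cells, most of all in libraries 1 and 2. Matk, a kinase that restrains Src-family kinases, rose by 2.18 ± 0.29 (SE, log2; edgeR adjusted p 0.00188). Sh2d6, an SH2-domain adaptor, rose by 2.69 ± 0.38 (67.5 ± 29.7 against 10.5 ± 3.51 CPM, SD, n = 3; edgeR adjusted p 0.00275). Hmx2, a homeobox factor, rose by 3.26 ± 0.52 (edgeR adjusted p 0.00446). It stood at 2.66 ± 0.70 against 0.27 ± 0.12 CPM (SD, n = 3), the latter near the level of 3 counts. Of the 22 tested members (24 listed), 14 were higher, 0 lower and 8 did not pass, and 21 were higher when adjusted over the list alone. For the tuft list, the median was 2.21 and the camera adjusted p 7.88e-12, and adjusted p = 0.262 with an estimated correlation (fry adjusted p 0.0629, range over alternatives 2.41e-50 to 0.262). Relative to the Lgr5-CreER mean, the list's median log2 level was 2.78, 2.53 and 0.63 in Hopx-CreER libraries 1, 2 and 3. The higher count was 21 without Hopx-CreER library 3, 8 without Hopx-CreER library 2, and 5, 5 and 6 without Lgr5-CreER library 1, 2 and 3.

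Enterocyte genes were higher in Hopx-CreER cells and highest in library 3. Fabp1 and Fabp2, which encode fatty acid binding proteins, rose by 3.07 ± 0.30 and 1.51 ± 0.19 (SE, log2; edgeR adjusted p 0.000638 and 0.00141). Fabp1 stood at 399 ± 161 CPM against 47.4 ± 14.2 CPM (SD, n = 3). Mttp, which loads lipid onto apolipoprotein B, rose by 1.32 ± 0.17 (edgeR adjusted p 0.00178). Of the 30 tested members, 24 were higher, 0 lower and 6 did not pass, with 27 higher and 1 lower when adjusted over the list alone. For the enterocyte list, the median was 2.38 and the camera adjusted p 1.47e-18, and adjusted p = 0.151 with an estimated correlation. Relative to the Lgr5-CreER mean, the list's median log2 level was 1.76, 1.85 and 3.11 in Hopx-CreER libraries 1, 2 and 3, and its median fold change without library 3 was 1.74. The higher count was 14, 13 and 17 without Lgr5-CreER libraries 1, 2 and 3. With GC offsets, 1 member was lower. Krt20 is also in the epithelial identity list.

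**Figure D2:**
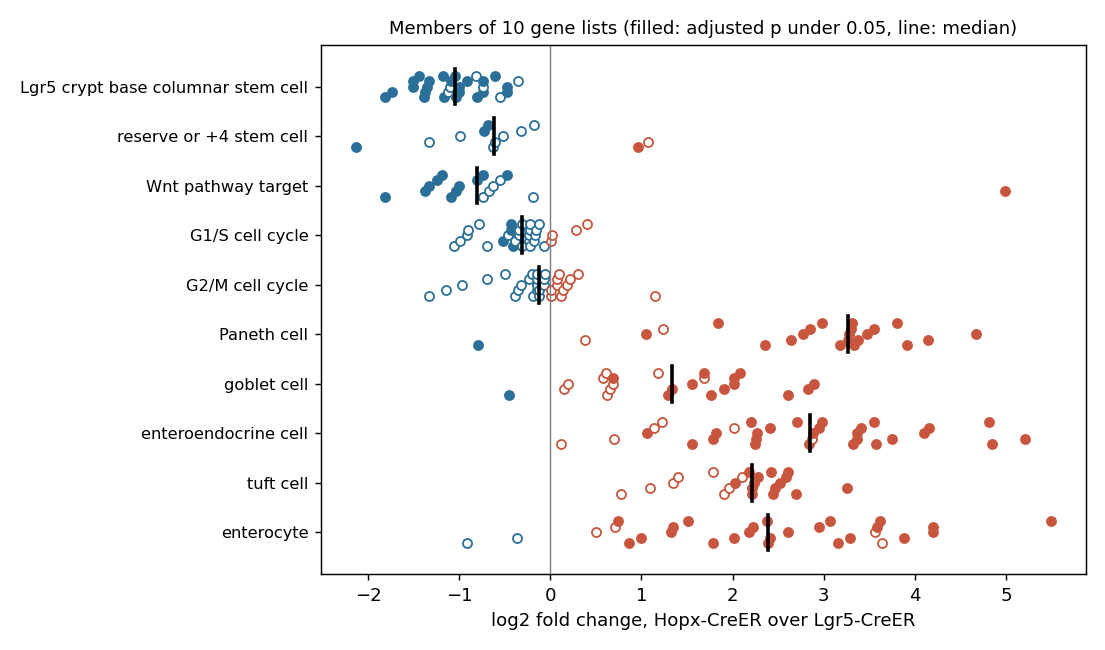
Log2 fold change, Hopx-CreER over Lgr5-CreER, of each tested member of 10 gene lists, with filled points for genes at an edgeR adjusted p under 0.05 and a line at each list's median. Medians lie at -1.04 for the Lgr5 stem cell list, 3.27 for the Paneth list, 2.85 for the enteroendocrine list and 2.38 for the enterocyte list, and no G2/M gene is filled.

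G1/S genes were lower in Hopx-CreER cells as a list by camera, while few passed singly. The 4 lower members of the G1/S list were Mcm6, Mcm3 and Mcm2, subunits of the replicative helicase, and Rrm1, the large subunit of ribonucleotide reductase. Mcm6 fell by 0.52 ± 0.10 (SE, log2; 543 ± 34.7 against 781 ± 14.4 CPM, SD, n = 3; edgeR adjusted p 0.00926), and kept its call without any 1 library. Rrm1 fell by 0.44 ± 0.12 (edgeR adjusted p 0.0389), Mcm3 by 0.41 ± 0.11 (0.0424) and Mcm2, named after its values were seen, by 0.44 ± 0.12 (0.0494). The calls of these 3 genes ended without Hopx-CreER library 2 or any 1 Lgr5-CreER library, and those of Mcm3 and Mcm2 without Hopx-CreER library 1 too, at adjusted p of up to 0.126, 0.144 and 0.161 for Rrm1, Mcm3 and Mcm2. Rrm1 was also not called with GC offsets (range over alternatives 0.017 to 0.133), nor Mcm3 with RLE factors (range 0.00866 to 0.144). Of the 30 tested members, 0 were higher, 4 were lower and 26 did not pass, with 1 higher and 6 lower when adjusted over the list alone. For the G1/S list, the median was -0.31 and the camera adjusted p 0.000433, and adjusted p = 0.151 with an estimated correlation. The lower count was 9 with GC offsets, 9 without Hopx-CreER library 3, and 1 without Hopx-CreER library 2 or any 1 Lgr5-CreER library.

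No mitotic gene of the G2/M list passed by edgeR. Mki67, the proliferation marker, had a log2 fold change of -1.33 ± 0.41 (SE; 1.08 ± 0.35 against 2.75 ± 0.48 CPM, SD, n = 3; edgeR adjusted p 0.0642), and passed with the filter of 10 counts and with GC offsets (range over alternatives 0.0445 to 0.213). Cenpf, a kinetochore protein, had -1.14 ± 0.47 (edgeR adjusted p 0.155), and Hjurp, a chaperone of centromeric histone, 0.31 ± 0.10 (edgeR adjusted p 0.0794), which passed by limma-voom with quality weights (adjusted p 0.0384; range over alternatives 0.0384 to 0.214). By edgeR, 0 of the 31 tested members (32 listed) were higher, 0 lower and 31 did not pass, and 0 passed when adjusted over the list alone. At an unadjusted p under 0.05, 3 members passed, the genes just named, and DESeq2 and limma-voom without quality weights called 0, while 1 member was lower with GC offsets. For the G2/M list, the median was -0.12 and the camera adjusted p 0.22, and adjusted p = 0.557 with an estimated correlation. The G2/M median was -0.24 with library totals alone and -0.0093 without Hopx-CreER library 3.

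Some inhibitors of cyclin-dependent kinases rose in Hopx-CreER cells. Cdkn1b and Cdkn2c, named after their values were seen, did not pass (edgeR adjusted p 0.486 and 0.273). Cdkn1a, which encodes the inhibitor p21, rose by 2.65 ± 0.21 (SE, log2), from 22.8 ± 2.34 to 143 ± 37.3 CPM (SD, n = 3; edgeR adjusted p 0.000374). Btg2, an antiproliferative gene that is also in the immediate early list, rose by 1.25 ± 0.11 (edgeR adjusted p 0.000512). The other higher members, named after their values were seen, were Cdkn2b at 2.56 ± 0.31 (edgeR adjusted p 0.00122), Cdkn1c at 2.25 ± 0.36 (0.0047) and Cdkn2d at 1.08 ± 0.23 (0.0151), each an inhibitor of cyclin-dependent kinases. The Cdkn2d call ended without Lgr5-CreER library 2 (adjusted p 0.0703). Of the 15 tested members (16 listed), 5 were higher, 0 lower and 10 did not pass, and 5 were higher when adjusted over the list alone. For the inhibitor and quiescence list, the median was 0.35 and the camera adjusted p 9.5e-05, and adjusted p = 0.0992 with an estimated correlation.

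The receptors Notch1 and Notch2 were lower in Hopx-CreER cells. Notch2 fell by 1.41 ± 0.24 (SE, log2; 12.7 ± 1.06 against 33.8 ± 9.75 CPM, SD, n = 3; edgeR adjusted p 0.00585), and Lfng, a glycosyltransferase that modifies Notch receptors, by 0.85 ± 0.16 (edgeR adjusted p 0.0096). Notch1, named after its values were seen, fell by 1.23 ± 0.27 (edgeR adjusted p 0.0167), a call that ended without Hopx-CreER library 1 (adjusted p 0.0539). Of the 15 tested members (20 listed), 0 were higher, 3 were lower and 12 did not pass, and 4 were lower when adjusted over the list alone. For the Notch list, which shares Dll1 with the reserve list, the median was -0.18 and the camera adjusted p 0.037, and adjusted p = 0.232 with an estimated correlation. The median was -0.29 with library totals alone and -0.36 with GC offsets. Its camera call ended without Hopx-CreER library 1 (adjusted p 0.112) or Lgr5-CreER library 1 (0.0573), in a range of 0.00304 to 0.232 over the alternatives.

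Several BMP response genes were higher in Hopx-CreER cells. Bambi, a BMP pseudoreceptor, rose by 1.67 ± 0.25 (SE, log2; edgeR adjusted p 0.00357), and Id3, a BMP-induced inhibitor of bHLH factors, by 1.55 ± 0.26 (259 ± 114 against 88.3 ± 7.35 CPM, SD, n = 3; edgeR adjusted p 0.00561). The other higher members, named after their values were seen, were Id1 at 1.34 ± 0.25 (edgeR adjusted p 0.00825), the ligand Bmp2 at 1.72 ± 0.36 (0.015) and the inhibitory Smad6 at 1.37 ± 0.30 (0.0167). The ligand Bmp7, also named after its values were seen, was lower at -0.83 ± 0.21 (edgeR adjusted p 0.0307). The Bmp2 call ended without Lgr5-CreER library 1 or 3 and the Smad6 call without Lgr5-CreER library 2 or 3 (adjusted p up to 0.073 and 0.0794), so that the higher count was 4, 4 and 3 without Lgr5-CreER library 1, 2 and 3. The lower count was 2 with GC offsets, 2 without Hopx-CreER library 3, and 0 without any 1 of the other libraries. Of the 13 tested members (20 listed), 5 were higher, 1 was lower and 7 did not pass, with 5 higher and 2 lower when adjusted over the list alone. For the BMP list, the median was 0.51 and the camera adjusted p 0.0535, and adjusted p = 0.182 with an estimated correlation. Without Hopx-CreER library 3 the BMP median was 0.30. It passed without Hopx-CreER library 2 (camera adjusted p 0.0327) or 3 (0.0408), with library totals alone (0.0404) and by fry (0.00513), in a range of 0.00513 to 0.182 over the alternatives.

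Genes tied to regeneration and YAP went both ways. Anxa5, an annexin, rose by 1.39 ± 0.26 (SE, log2; edgeR adjusted p 0.00856), and Clu, given above, was lower. The other called members, named after their values were seen, were the calcium-binding S100a6 at 1.45 ± 0.31 (edgeR adjusted p 0.0167), and, lower, the YAP partner Tead2 at -1.05 ± 0.24 (0.0219) and the YAP paralogue Wwtr1 at -0.89 ± 0.25 (0.0443). Of the 13 tested members (22 listed), 2 were higher, 3 were lower and 8 did not pass, with 3 higher and 3 lower when adjusted over the list alone. For the regenerative list, the median was 0.15, the mean 0.16 and the fry direction up, while camera ranked it down, with a camera adjusted p of 0.996, and adjusted p = 0.997 with an estimated correlation. The regenerative median was 0.0445 with library totals alone, 0.083 with the columns that share a number summed, 0.29 with GC offsets and 0.36 without Hopx-CreER library 3. Clu and Ly6a are also in the reserve list. Leaving out Hopx-CreER library 1 or 2 gave 2 higher and 1 lower, or 1 higher and 2 lower, and leaving out Lgr5-CreER library 1, 2 or 3 gave 4 and 1, 1 and 1, or 1 and 1.

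Fatty acid oxidation genes were higher in Hopx-CreER cells as a list by camera. Cpt2, a carnitine palmitoyltransferase, rose by 0.83 ± 0.10 (SE, log2; 388 ± 23.6 against 218 ± 15.2 CPM, SD, n = 3; edgeR adjusted p 0.00153). Of the 20 tested members, 8 were higher, 0 lower and 12 did not pass, and 13 were higher when adjusted over the list alone. For the fatty acid list, the median was 0.39 and the camera adjusted p 2.92e-06, and adjusted p = 0.151 with an estimated correlation. Its higher count was 4 without Lgr5-CreER library 2 and 4 without Lgr5-CreER library 3.

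Glycolytic and respiratory genes were also higher in Hopx-CreER cells as lists by camera. Pfkp, a phosphofructokinase, rose by 1.49 ± 0.14 (SE, log2; 387 ± 35.8 against 138 ± 21.3 CPM, SD, n = 3; edgeR adjusted p 0.000535), and Aldoa, an aldolase, by 0.77 ± 0.11 (edgeR adjusted p 0.00302). Cycs, which encodes cytochrome c, rose by 0.63 ± 0.12 (edgeR adjusted p 0.00851), and Uqcrfs1, the Rieske protein of complex III, by 0.63 ± 0.12 (edgeR adjusted p 0.00886). The Cycs call ended without Lgr5-CreER library 2 (adjusted p 0.0515; range over alternatives 0.000396 to 0.0515). Of the 19 tested glycolysis members (20 listed), 6 were higher, 0 lower and 13 did not pass, with 11 higher and 1 lower when adjusted over the list alone. For the glycolysis list, the median was 0.42 and the camera adjusted p 0.000151, and adjusted p = 0.281 with an estimated correlation. Its higher count was 4, 3 and 4 without Lgr5-CreER libraries 1, 2 and 3, and 1 member was lower under GC offsets. Of the 25 tested oxidative phosphorylation members (27 listed), 8 were higher, 0 lower and 17 did not pass, and 16 were higher when adjusted over the list alone. For the oxidative phosphorylation list, the median was 0.34 and the camera adjusted p 3.43e-05, and adjusted p = 0.268 with an estimated correlation. Its higher count was 5 and 4 without Hopx-CreER libraries 2 and 3, and 3, 1 and 2 without Lgr5-CreER libraries 1, 2 and 3. With GC offsets the oxidative phosphorylation count was 3, and with library totals alone the list's median was 0.22.

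Ribosome biogenesis genes were slightly lower in Hopx-CreER cells as a list. The single called gene was Mybbp1a, a nucleolar regulator of rRNA synthesis, which fell by 0.46 ± 0.13 (SE, log2; 372 ± 32.4 against 512 ± 73.9 CPM, SD, n = 3; edgeR adjusted p 0.0468). Polr1a, the large subunit of RNA polymerase I, had -0.66 ± 0.19 (edgeR adjusted p 0.0525), and passed with library totals alone, upper quartile factors, DESeq2, no filter, the filter of 10 counts and GC offsets, and without Hopx-CreER library 1 (0.0481) or Lgr5-CreER library 3 (0.0448; range over alternatives 0.0179 to 0.183). Of the 23 tested members, 0 were higher, 1 was lower and 22 did not pass, and 9 were lower when adjusted over the list alone. For the ribosome biogenesis list, the median was -0.36 and the camera adjusted p 7.7e-05, and adjusted p = 0.0957 with an estimated correlation. The lower count was 12 with GC offsets, and it was 2, 0 and 5 without Hopx-CreER libraries 1, 2 and 3, and 0, 0 and 2 without Lgr5-CreER libraries 1, 2 and 3. Mybbp1a lost its call without any 1 library but Hopx-CreER library 3 (adjusted p 0.0643 to 0.151) and with RLE factors (0.052), in a range of 0.00869 to 0.151.

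Genes of the unfolded protein response and secretory machinery were slightly higher in Hopx-CreER cells as a list by camera. Atf4, a stress-responsive transcription factor, rose by 0.58 ± 0.12 (SE, log2; 271 ± 32.2 against 181 ± 13.8 CPM, SD, n = 3; edgeR adjusted p 0.0137), and Xbp1, a transcription factor of secretory cells, by 0.51 ± 0.11 (edgeR adjusted p 0.0172). The Atf4 call ended without Lgr5-CreER library 2 (adjusted p 0.0741) or 3 (0.061), with a range of 0.00245 to 0.0741, and the Xbp1 call without Lgr5-CreER library 1 (0.0592) or 2 (0.0857), with a range of 0.00383 to 0.0857. Of the 27 tested members, 6 were higher, 0 lower and 21 did not pass, and 10 were higher when adjusted over the list alone. For the unfolded protein response list, the median was 0.20 and the camera adjusted p 0.0183, and adjusted p = 0.316 with an estimated correlation. That median was 0.082 with library totals alone and 0.075 with GC offsets. The higher count was 2 and 3 without Hopx-CreER libraries 1 and 2, and 1, 0 and 1 without Lgr5-CreER libraries 1, 2 and 3. The camera call ended without Hopx-CreER library 1 (adjusted p 0.0889) or 2 (0.0628), in a range of 0.00118 to 0.316.

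MHC class II genes were lower in Hopx-CreER cells, in a comparison carried by Lgr5-CreER libraries 2 and 3. H2-Eb1 and H2-Ab1, chains of the antigen-presenting molecules, fell by 0.93 ± 0.20 and 0.90 ± 0.23 (SE, log2; edgeR adjusted p 0.0167 and 0.0313). H2-Ab1 stood at 1330 ± 134 CPM in Hopx-CreER cells and at 2474 ± 812 CPM in Lgr5-CreER cells (SD, n = 3), where its libraries gave 1560, 2740 and 3120 CPM. The other lower members, named after their values were seen, were H2-Aa at -0.92 ± 0.24 (edgeR adjusted p 0.0385), the invariant chain Cd74 at -0.70 ± 0.19 (0.0401) and Ciita, the master regulator of class II transcription, at -1.15 ± 0.33 (0.0496). Of the 8 tested members (9 listed), 0 were higher, 5 were lower and 3 did not pass, and 8 were lower when adjusted over the list alone. For the MHC class II list, the median was -0.91 and the camera adjusted p 0.00012, and adjusted p = 0.297 with an estimated correlation (fry adjusted p 0.104; range over alternatives 1.94e-17 to 0.297). Ms4a1 and Lck, markers of B and T cells, were lower in Hopx-CreER cells too, while the B cell gene Cd79b was uncalled at 0.99 ± 0.38 (SE; edgeR adjusted p 0.129). Relative to the Hopx-CreER mean, the list's median log2 level was 0.13, 1.05 and 1.24 in Lgr5-CreER libraries 1, 2 and 3. The lower count was 8 without Lgr5-CreER library 1, 1 without Hopx-CreER library 1, and 0 without Hopx-CreER library 2, Lgr5-CreER library 2 or Lgr5-CreER library 3. The H2-Ab1 call ended without Hopx-CreER library 1 (adjusted p 0.0688) or 2 (0.0674) or Lgr5-CreER library 2 (0.112) or 3 (0.119), and the H2-Eb1 call without Hopx-CreER library 2 (0.0515) or Lgr5-CreER library 2 (0.0704) or 3 (0.0658).

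Interferon response genes did not pass as a list by camera. Usp18, a protease that removes ISG15, rose in Hopx-CreER cells by 2.57 ± 0.49 (SE, log2; 11.5 ± 2.17 against 1.93 ± 1.15 CPM, SD, n = 3; edgeR adjusted p 0.00925). Bst2, a membrane protein that tethers virions, had -0.62 ± 0.19 (edgeR adjusted p 0.0639), and passed by DESeq2, by voom with quality weights, with library totals alone, with GC offsets and without Hopx-CreER library 3 (0.0284) (range over alternatives 0.0123 to 0.227). Of the 18 tested members (23 listed), 1 was higher, 0 were lower and 17 did not pass, and 1 was higher when adjusted over the list alone. For the interferon list, the median was -0.044 and the camera adjusted p 0.741, and adjusted p = 0.895 with an estimated correlation. Without Hopx-CreER library 1, 3 or Lgr5-CreER library 1, 1 member was lower, 2 were higher without Hopx-CreER library 3, and 2 were lower with GC offsets. The interferon median was -0.16 with library totals alone, -0.085 with upper quartile factors, -0.18 with GC offsets and -0.21 without Hopx-CreER library 3.

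Immediate early genes, which cell dissociation also induces, were higher in Hopx-CreER cells. Klf2, a Krüppel-like factor, rose by 1.97 ± 0.30 (SE, log2; 9.37 ± 1.73 against 2.38 ± 0.27 CPM, SD, n = 3; edgeR adjusted p 0.00366), and Btg2 is given above. Atf3, a stress-induced transcription factor named after its values were seen, was 315 ± 164 CPM against 54.9 ± 28.1 CPM (SD, n = 3). Myc, the single lower member and also a Wnt target, fell by 0.74 ± 0.16 (edgeR adjusted p 0.0167), a call that ended without Lgr5-CreER library 2 or 3 (adjusted p 0.0639 to 0.0683). Of the 23 tested members (24 listed), 12 were higher, 1 was lower and 10 did not pass, with 17 higher and 2 lower when adjusted over the list alone. For the immediate early list, the median was 1.17 and the camera adjusted p 1.01e-08, and adjusted p = 0.162 with an estimated correlation. Relative to the Lgr5-CreER mean, the list's median log2 level was 1.17, 0.96 and 1.48 in the Hopx-CreER libraries, and 0.68, -0.32 and -0.26 in Lgr5-CreER libraries 1, 2 and 3. The counts were 7 higher and 0 lower without Lgr5-CreER library 2 or 3, and 11 higher and 2 lower without Hopx-CreER library 2.

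**Figure D3:**
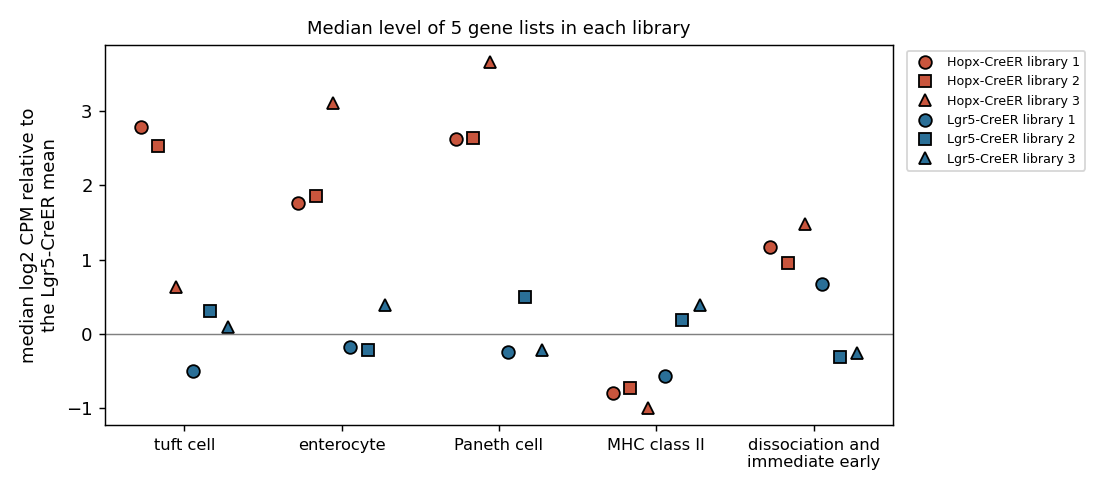
Median log2 CPM, relative to the Lgr5-CreER mean, of the tuft, enterocyte, Paneth, MHC class II and immediate early lists, with 1 point per library. Hopx-CreER library 3 lies low for tuft genes (0.63) and high for enterocyte genes (3.11), and Lgr5-CreER library 1 lies at -0.56 for MHC class II genes and at 0.68 for immediate early genes.

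Most markers of blood and stromal cells were scarce in both groups, and few could be tested. Ms4a1, the B cell antigen CD20, named after its values were seen, had 1 count in Hopx-CreER libraries against 45 in Lgr5-CreER libraries, a ratio of 39.3 (95% interval 6.71 to 1590) in favour of Lgr5-CreER. Lck, a T cell kinase, fell by 1.48 ± 0.32 (SE, log2; 2.39 ± 0.27 against 6.66 ± 1.65 CPM, SD, n = 3; edgeR adjusted p 0.0175), and Cd79b, a part of the B cell receptor, had 0.99 ± 0.38 (edgeR adjusted p 0.129). Of the 6 tested immune genes (28 listed), 0 were higher, 2 were lower and 4 did not pass, and 2 were lower when adjusted over the list alone. For the immune list, the median was -0.094, the mean -0.82 and the camera adjusted p 0.188, and adjusted p = 0.406 with an estimated correlation. The immune median did not keep its sign, at 0.31 with the 2 columns that share a number summed, against -0.67 without Hopx-CreER library 3, -0.21 with library totals alone and -0.17 with GC offsets. The Lck call ended without Hopx-CreER library 1 (adjusted p 0.0527) or 2 (0.0549) or Lgr5-CreER library 2 (0.0592) or 3 (0.0888), which left 1 lower gene. Vim, an intermediate filament gene, was the single called stromal marker, at 28 ± 4.79 against 2.56 ± 0.65 CPM (SD, n = 3), a rise of 3.44 ± 0.27 (edgeR adjusted p 0.000374), while the endothelial Pecam1 had 1.51 ± 0.88 (0.306). Of the 5 tested stromal genes (24 listed), 1 was higher, 0 lower and 4 did not pass, and 1 was higher when adjusted over the list alone. For the stromal list, the median was 0.57 and the camera adjusted p 0.0183, and adjusted p = 0.151 with an estimated correlation, and the call ended with no filter (0.111; range over alternatives 0.00244 to 0.151). With GC offsets the stromal median was 0.36. None of the 8 erythroid genes listed passed the count filter, so 0 were tested.

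Epithelial identity genes were slightly higher in Hopx-CreER cells as a list by camera. Krt8, a keratin of simple epithelia, rose by 1.00 ± 0.12 (SE, log2; 6471 ± 656 against 3228 ± 190 CPM, SD, n = 3; edgeR adjusted p 0.00122), and Krt19, given above and shared with the reserve list, also rose. Of the 16 tested members, 7 were higher, 0 lower and 9 did not pass, with 8 higher and 1 lower when adjusted over the list alone. For the epithelial list, the median was 0.31 and the camera adjusted p 0.000434, and adjusted p = 0.0992 with an estimated correlation. Its higher count was 6, 4 and 5 without Lgr5-CreER libraries 1, 2 and 3. The epithelial median was 0.20 with library totals alone and 0.11 with GC offsets, under which 1 member was lower.

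Genes of the proximal and distal small intestine did not pass as lists by camera. Slc40a1, the iron exporter ferroportin, rose by 1.49 ± 0.37 (SE, log2; edgeR adjusted p 0.0307), a call that ended without Hopx-CreER library 1 (adjusted p 0.0532) or 2 (0.105) or Lgr5-CreER library 1 (0.108) or 2 (0.125), in a range of 0.000528 to 0.125. Cyp2b10, a cytochrome P450, was the other called proximal gene. Of the 10 tested proximal genes, 2 were higher, 0 lower and 8 did not pass, with 3 higher and 1 lower when adjusted over the list alone. For the proximal list, which shares Gkn3 with the Lgr5 stem cell list, the median was 0.33 and the camera adjusted p 0.22, and adjusted p = 0.321 with an estimated correlation, though fry gave 0.00513 (range over alternatives 0.00513 to 0.342), and the median was 0.21 with library totals alone. Its higher count was 1 without any 1 Hopx-CreER library or without Lgr5-CreER library 3, with 1 lower without Hopx-CreER library 3, and 0 without Lgr5-CreER library 1 or 2. Ces1f, a carboxylesterase and the single called distal gene, rose by 2.73 ± 0.26 (131 ± 40.2 against 19.6 ± 5.74 CPM, SD, n = 3; edgeR adjusted p 0.000569), and Amn, a part of the vitamin B12 receptor, had 0.63 ± 0.22 (edgeR adjusted p 0.104). Of the 6 tested distal genes (15 listed), 1 was higher, 0 lower and 5 did not pass, and 1 was higher when adjusted over the list alone. For the distal list, the median was 0.016, and -0.098, -0.026 and -0.098 with library totals alone, upper quartile factors and GC offsets, -0.011 with the columns that share a number summed, and 0.04 without Hopx-CreER library 3. The camera adjusted p was 0.118 for the distal list, and adjusted p = 0.321 with an estimated correlation, and it passed without Lgr5-CreER library 3 (0.0442; range over alternatives 0.0442 to 0.422).

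Mitochondrially encoded and sex-linked genes did not pass the test. The complex I genes mt-Nd1 and mt-Nd3 had log2 fold changes of -0.48 ± 0.25 and -0.45 ± 0.33 (SE; edgeR adjusted p 0.242 and 0.413). By edgeR, 0 of the 8 tested mitochondrial members (13 listed) were higher, 0 lower and 8 did not pass, and 0 passed when adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or by limma-voom without quality weights. For the mitochondrial list, the median was -0.35 and the camera adjusted p 0.129, and adjusted p = 0.615 with an estimated correlation. Its median was -0.18 with GC offsets and -0.15 without Hopx-CreER library 3. Without Hopx-CreER library 2 it had 1 lower member, mt-Nd1 (edgeR adjusted p 0.0436), and a camera adjusted p of 0.00194 (range over alternatives 0.00194 to 0.636). The Y-linked genes Kdm5d and Eif2s3y had -0.69 ± 0.42 and -0.52 ± 0.38 (edgeR adjusted p 0.327 and 0.41), and their counts were above 0 in all 6 libraries. By edgeR, 0 of the 4 tested sex-linked members (6 listed) were higher, 0 lower and 4 did not pass, and 0 passed when adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or by limma-voom without quality weights. For the sex-linked list, the median was -0.53 and the camera adjusted p 0.335, and adjusted p = 0.632 with an estimated correlation. The sex-linked median was -0.29 without Hopx-CreER library 3.

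Across the 29 lists tested, camera with a preset correlation of 0.01 called 13 higher and 7 lower in Hopx-CreER cells, and fry called 14 higher and 6 lower. With an estimated correlation, camera called 0 lists, the smallest adjusted p being 0.0521, and 7 had an unadjusted p under 0.05. For each of the 20 called lists, that setting gave the highest adjusted p of all alternatives. With the 2 columns that share a number summed, the lower count was 14 for the stem cell list, 6 for Wnt, 1 for G1/S, 0 for ribosome biogenesis and 0 for MHC class II. In that setting the higher count was 6 for tuft, 15 for enterocyte, 4 for fatty acid oxidation, 2 for oxidative phosphorylation, 1 for the unfolded protein response and 7 for immediate early genes. Summing also ended the calls of Cyp2b10, Slc28a1, Lct, Fstl4, Alox15, Nlrc5, Rrm1, Mcm3, Mybbp1a, Atf4, H2-Eb1, H2-Ab1, Lck and Slc40a1 (edgeR adjusted p 0.0516 to 0.131).

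Among called genes at 10 CPM or more whose libraries did not overlap between groups, predicted genes aside, the 6 largest rises were in Afp, Ucn3, Cyp2b10, Gpx3, Slc28a1 and Lct. Afp, which encodes alpha-fetoprotein, rose by 8.35 ± 0.63 (SE, log2), from 0.75 ± 0.48 to 256 ± 149 CPM (SD, n = 3; edgeR adjusted p 0.000374). Ucn3, which encodes the peptide urocortin 3, had 591 counts in Hopx-CreER libraries against 2 in Lgr5-CreER libraries, a ratio of 338 (95% interval 93.2 to 2800; edgeR adjusted p 0.000528). Gpx3, a secreted glutathione peroxidase, rose by 5.55 ± 0.66 (70.3 ± 46.6 against 1.52 ± 0.76 CPM; edgeR adjusted p 0.00122). Cyp2b10, the nucleoside transporter gene Slc28a1 and the lactase gene Lct rose by 6.02 ± 1.67, 5.51 ± 1.25 and 5.49 ± 1.2 (edgeR adjusted p 0.0455, 0.0209 and 0.0177), mostly in Hopx-CreER library 3. Cyp2b10 was 1.21, 2.11 and 77.9 CPM in Hopx-CreER libraries 1, 2 and 3, Slc28a1 was 9.04, 1.69 and 49.4 CPM, and Lct was 8.14, 5.67 and 97.5 CPM. Without Hopx-CreER library 3 the log2 fold change was 2.01 for Cyp2b10 (edgeR adjusted p 0.136), 3.62 for Slc28a1 (0.018) and 3.08 for Lct (0.00439). Without Lgr5-CreER library 1, 2 or 3 the adjusted p was 0.133, 0.154 or 0.13 for Cyp2b10, 0.0809, 0.0822 or 0.0625 for Slc28a1 and 0.071, 0.0794 or 0.0597 for Lct. By limma-voom without quality weights none of these 3 passed, nor did Cyp2b10 (0.124) or Slc28a1 (0.05) with them or Cyp2b10 with library totals alone (0.0546), and the adjusted p over the alternatives ran from 0.000241 to 0.236 for Cyp2b10, 3.15e-05 to 0.118 for Slc28a1 and 1.37e-05 to 0.105 for Lct.

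The 6 largest falls among such genes were in BC002163, Cap1, Fstl4, Alox15, Nlrc5 and Tnfrsf19. BC002163, a processed pseudogene on chromosome 16 (42955631 to 42955949, GRCm38), fell by 2.89 ± 0.37 (SE, log2; 3.62 ± 0.49 against 26.9 ± 13.6 CPM, SD, n = 3; edgeR adjusted p 0.00164). Cap1, an actin regulator on chromosome 4 (122859047 to 122886056), fell by 2.24 ± 0.25 (37.4 ± 3.68 against 176 ± 69.2 CPM; edgeR adjusted p 0.000979). Fstl4, a follistatin-like gene, fell by 2.23 ± 0.46 (edgeR adjusted p 0.0134), Alox15, a lipoxygenase, by 1.98 ± 0.51 (0.0339) and Nlrc5, a regulator of MHC class I genes, by 1.90 ± 0.39 (0.0136). The Fstl4 call ended without Lgr5-CreER library 2 (adjusted p 0.0606; range over alternatives 2.09e-06 to 0.0606), and the Nlrc5 call without Hopx-CreER library 2 (0.0516) or Lgr5-CreER library 2 (0.0612; range 1.36e-05 to 0.0612). The Alox15 call ended without Hopx-CreER library 2 (adjusted p 0.106) or Lgr5-CreER library 2 (0.132) or 3 (0.111) and by limma-voom without (0.0715) and with quality weights (0.0569; range 0.00088 to 0.132).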

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

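The GC offsets and both settings that sum 2 columns were chosen after the data were seen, while the other alternatives were fixed beforehand. No called result reversed its direction under any alternative run. Settings that leave 5 or fewer libraries also leave fewer residual degrees of freedom, so calls can end there with fold changes little changed. No paired analysis was possible because the columns carry no replicate number, so the replicate block was not run. Of 63 named genes past the threshold, 45 passed it under every alternative and 47 under each one that left out no library; DESeq2 gave no adjusted p for Cyp2b10 and Lct. The counts higher and lower in Hopx-CreER cells were 938 and 729 with library totals alone, 1413 and 670 by DESeq2, and 1044 and 1028 with GC offsets. The excess of higher over lower calls thus depended on the scaling, and the cause was not tested. Stricter thresholds kept fewer genes by construction: 654 (555 higher, 99 lower) at an adjusted p under 0.01, 939 (770 and 169) at a log2 fold change of at least 1, and 592 (532 and 60) by glmTreat. Summing the 2 columns that share a number, which leaves 5 libraries, gave 790 changed genes (659 and 131), and log2 fold changes of -0.75 for Hopx (edgeR adjusted p 0.0515) and -1.37 for Lgr5 (0.0585). Leaving out 1 library gave 723 to 1868 changed genes, 606 to 1275 higher and 117 to 593 lower, log2 fold changes of -0.86 to -0.59 for Hopx and -1.59 to -1.08 for Lgr5, and camera adjusted p of 0.0109 to 0.0522 for the reserve list, 0.0157 to 0.112 for Notch, 0.0327 to 0.0999 for BMP, 0.00118 to 0.0889 for the unfolded protein response, 0.0442 to 0.422 for distal and 0.00194 to 0.404 for mitochondrial genes. The BMP list passed with library totals alone (0.0404) and the stromal list did not with no filter (0.111); the cause was not tested. An estimated correlation gave camera adjusted p of 0.0521 for the Lgr5 stem cell list, 0.162 for reserve, 0.0992 for Paneth, 0.151 for goblet and 0.151 for enteroendocrine genes. It gave 0.262 for tuft, 0.151 for enterocyte, 0.151 for G1/S, 0.0992 for the cell cycle inhibitors, 0.0957 for Wnt and 0.232 for Notch genes. It gave 0.151 for fatty acid oxidation, 0.281 for glycolysis, 0.268 for oxidative phosphorylation, 0.0957 for ribosome biogenesis and 0.316 for the unfolded protein response. It gave 0.297 for MHC class II, 0.162 for immediate early, 0.151 for stromal and 0.0992 for epithelial genes. The estimates were 0.948 for MHC class II, 0.885 for tuft, 0.655 for enteroendocrine, 0.526 for goblet and 0.503 for Paneth genes, against the preset 0.01. They lay under the preset for ribosome biogenesis (-0.0175), stromal (-0.15) and epithelial genes (0.000773), whose adjusted p rose too. The size of the correlation thus cannot account for all of the rise. With an estimated correlation, camera also takes its p-value on the few residual degrees of freedom that 6 libraries leave, which raises it. For epithelial genes the unadjusted camera p went from 0.00024 with the preset to 0.0173 with the estimate, though the correlation was lower. How much of each rise is due to which was not tested. By fry, which puts another question, the adjusted p was 0.0629 for tuft, 0.104 for MHC class II, 0.00513 for BMP and 0.00513 for proximal genes. Over the 500 most variable genes the first component held 75.8% of the variance. In the simulation, which made 108 calls, folds of 1.5 were called for 11.9% of genes, so genes that changed by such folds may have been missed. With the 1586 calls of the real data the Benjamini-Hochberg cutoff is less strict, so that share need not hold there.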

Other observations

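In this part, the tests chosen only after the result was seen include those of the depth and the enterocyte RNA of Hopx-CreER library 3. They also include those of the libraries that carry the MHC class II difference, and of exchanged labels and the inserted allele for Hopx. The GC tests for MHC class II and Hopx, and the GC correction of library 3, rest on offsets that were likewise added after the data were seen.

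Beside Tph1 and Chga, 6 genes tied to serotonin-producing enterochromaffin cells were higher in Hopx-CreER cells. They were picked after their values were seen, and no fixed list or enrichment test stands behind them. Trpa1, an irritant-sensing ion channel, rose by 5.07 ± 0.55 (SE, log2; edgeR adjusted p 0.000926), and Lmx1a, a transcription factor of these cells, by 3.93 ± 0.33 (31.7 ± 9.04 against 2.08 ± 0.58 CPM, SD, n = 3; edgeR adjusted p 0.000418). Slc18a1, which loads monoamines into vesicles, rose by 2.79 ± 0.30 (edgeR adjusted p 0.000926), and Gch1, which makes the cofactor of tryptophan hydroxylase, by 2.15 ± 0.21 (0.000569). Ddc, which makes serotonin from its precursor, rose by 1.33 ± 0.16 (edgeR adjusted p 0.00123), and Maoa, which degrades it, by 1.48 ± 0.13 (0.000424). Neurog3, Atoh1 and Dll1 were also named after their values were seen. Neurog3, the factor that starts enteroendocrine differentiation, stood at 17.6 ± 3.22 CPM in Hopx-CreER cells and at 16.3 ± 4.45 CPM in Lgr5-CreER cells (SD, n = 3), a log2 fold change of 0.12 ± 0.26 (edgeR adjusted p 0.805). Atoh1, a factor of the secretory lineage, had 0.58 ± 0.29 (edgeR adjusted p 0.231), and the Notch ligand Dll1 had -0.18 ± 0.17 (0.536).

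The genes that follow were likewise picked after their values were seen and make no tested group. Cdhr5 and Cdhr2, protocadherins that link microvilli, rose in Hopx-CreER cells by 1.46 ± 0.10 and 1.19 ± 0.12 (SE, log2; edgeR adjusted p 0.00031 and 0.000658), and Espn, an actin-bundling protein, by 2.42 ± 0.21 (edgeR adjusted p 0.000439). Lower in Hopx-CreER cells were Smo, the Hedgehog signal transducer, at -1.15 ± 0.12 (edgeR adjusted p 0.000819), the phosphatase Ptprs at -1.58 ± 0.16 (0.000677), Cdk6, a kinase of the G1 phase, at -1.41 ± 0.23 (0.00505), the carbonic anhydrase Car12 at -1.37 ± 0.14 (0.000655) and the pore-forming claudin Cldn2 at -0.82 ± 0.10 (0.00153). Each gene named in this paragraph kept its call without any 1 library.

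Hopx-CreER library 3 lay apart from the other Hopx-CreER libraries, with an SD of its log2 deviation from their mean of 0.689 over all tested genes, against 0.52 between libraries 1 and 2 over the same genes. The first is taken from a mean of 2 libraries and the second between single libraries. With equal spread the first would be the smaller, so the 2 values understate how far library 3 lay apart. Low depth is argued against, since the total of Hopx-CreER library 3, 11.4M counts, exceeded that of Lgr5-CreER library 2, which did not stand apart. Its deviation followed transcript length (Spearman rho -0.371) and transcript GC content (0.473) across genes, which are not independent replicates. Whether the GC trend is technical was not tested. That trend may account for part of the deviation, and taking it out lowered the SD to 0.613. After that correction, the enterocyte list still lay 1.35 above libraries 1 and 2 (median, log2), with the Paneth list at 0.971 and the tuft list at -1.88, so a different mix of cells in that library is a candidate explanation for what remained. Among the Hopx-CreER columns, its name alone carries an added tag whose meaning the labels do not give, and why the mix would differ was not tested.

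The fall of MHC class II genes is not accounted for by a GC trend, since with GC offsets the list's median fold change was 1.11 times its value without them. The excess of Lgr5-CreER library 1 over the Hopx-CreER mean was 0.12 of that of the other two Lgr5-CreER libraries, whose column names share a number, so the difference may rest on a single mouse or preparation. In the same library 1, 11 of the 12 called immediate early genes lay above both other Lgr5-CreER libraries. Of B cell genes, Ms4a1 was 0.80, 1.30 and 1.24 CPM in the Lgr5-CreER libraries and at most 0.075 CPM in the others. Cd79b was 2.34, 1.64 and 2 CPM in the Lgr5-CreER libraries against 2.64, 3.97 and 5.38 CPM in the others. Cd79a, which like Ms4a1 was named after its values were seen, was at most 0.278 CPM anywhere. Such counts are too few to settle a share of blood cells. A biological difference between the cells that the 2 alleles mark stays open and untested.

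Hopx transcript was lower in the cells sorted through the Hopx allele. Exchanged group labels are argued against, since 23 of 29 tested Lgr5 stem cell genes were lower in the libraries named Hopx-CreER, and so is a GC trend, since the log2 fold change of Hopx was -0.67 ± 0.16 (SE) with GC offsets. An inserted CreER that stops the Hopx transcript from 1 allele could lower its level, and the fold change of -0.73 ± 0.15 cannot be told apart from that effect, because the structure of the allele is not in the labels. A lower Hopx level in the cells that the allele marks stays open and untested.

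Sequence from another mouse strain can flank an engineered locus and shift counts of nearby genes, which was tested as a hypothesis. Of 104 tested genes within 10 Mb of Hopx or Lgr5, 6 were called (5.77%), against 12.8% elsewhere, a ratio of 0.451 (one-sided Fisher's exact p 0.994), so no excess of calls lay near either locus.

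The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1586 genes and the highest of the others 0 by edgeR, so 1 of the 10 splits, the real one itself, gave as many genes. Every other split mixes libraries of both groups, which puts the group difference into its within-group spread. Few gene calls would follow from that alone, so these splits do not show what chance gives. For lists by camera, the real split called 20 and the others 7 to 14, and again the real split was the 1 of the 10 that gave as many lists. Camera with the preset correlation thus called lists in splits where edgeR called 0 genes. Each of the other splits keeps a part of the group difference, so for lists too they do not show what chance gives.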
